A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

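Per the labels' protocols, cultures grew to an OD600 of 0.25 at 30 °C in selective synthetic complete medium. DTT was given at 2 mM for 1 h before harvest. A tunicamycin treatment is mentioned there too, but no sample of it is present. Total RNA was extracted with hot acid phenol and cleaned on a column, and 100 ng was labelled with Cy3 under version 6.5 of the manufacturer's single-colour protocol. How spike-in RNA was added is not given in the sources used here. Per the file headers, the arrays were scanned on an Agilent scanner and extracted with Agilent Feature Extraction 10.7.1.1, which subtracted background and removed spatial trends per spot. Per the file headers, the processed signal is in intensity units and is not scaled between arrays, and the probe design names the sacCer1 build. The reference table used for names follows another build, so loci are given by systematic name and without coordinates.

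The series also holds an authors' table of log2 values with 5742 probes, 12 of them controls. As deposited by the authors, it holds log2 signal scaled per array and centred per probe on the median over the arrays, as its values show. Its columns had medians from −0.0332 to 0.0290. After the same centring the scanner files' values correlated with each column across probes with r from 0.985 to 0.999 and slopes from 0.903 to 1.01, so scale, centring and direction are known from the values, while the authors' steps are not given in the sources used here. That table leaves out 886 yeast probes, 399 of them well above background in some group. All 15 columns were matched to samples (0 not mapped). It served as an alternative.

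The values used here came from the processed signal of the 61657 yeast spots per array. Spots marked as non-uniform outliers were left out (5 to 37 per array). The remaining spots of a probe, of which there are 9 or 10, were averaged on the log2 scale, and the array's 75th percentile was subtracted. Probes of a gene were averaged. Of 6572 genes, 6529 had 1 probe and 43 had more. Among 34 tested genes with several probes, the probes differed in sign for 2 genes in DTT, 5 in alg5, 1 in lhs1 and 5 in scj1, with a largest range of 1.18 log2. Names were matched to the reference by locus tag for 5936 probes, by accession for 1 and by synonym for 4, and 675 kept the name in the files. A gene was tested if at least 1 probe was well above background on all 3 arrays of at least 1 group, which left 6095 genes and took out 477.

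Genes were tested in R 4.3.3 with limma 3.58.1, and files were read with data.table version 1.17.8. A single fit over all 15 arrays with 10 residual degrees of freedom gave 10 two-sided comparisons, with Benjamini-Hochberg adjustment over all tested genes within each and a threshold of 0.05. An exact test of 3 against 3 arrays cannot go below 0.1, so no rank test per gene was run. Every p attached to a gene is from limma, and every p attached to a list is from camera in limma with a preset correlation of 0.01, adjusted over the 29 lists. Camera was repeated with the correlation estimated per list, and fry was run as an alternative. Fry asks whether the genes of a list move on balance in one direction and does not compare them with other genes.

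Where a gene was well above background on 0 of 3 arrays of a group, its difference is given as at least N-fold, from the mean of the higher group and the mean of the lower group with each array set to its floor where it lay under it. No fold is given where that bound is under 1, as for YPT53 in scj1 against WT. An array's floor is the lowest log2 value among its probes that are well above background. The text says where only some arrays measured a gene.

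Named genes followed a rule. For the 4 comparisons with WT they were up to 8 genes per direction with the largest change among those past the threshold whose 3 arrays lay all on one side of the 3 WT arrays, and which were well above background on all 3 arrays of the higher group. Up to 4 members with the largest change were named from each list that passed or had at least 3 members called. For the other 6 comparisons the rule took up to 5 per direction. Added whatever their value were ALG5, LHS1, SCJ1, KAR2, PDI1, ERO1, EUG1, HAC1, DER1, HRD1, INO1, SEC61, SIL1, JEM1 and the auxotrophic and mating type markers. The text prints part of these.

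The 29 lists were ER folding, UPR signalling, ER-associated degradation, N-glycosylation, O-mannosylation, GPI anchor, ER translocation, ER to Golgi transport, inositol and phospholipid, ergosterol, cell wall integrity, cytosolic heat shock, general stress, redox and Yap1, sulfur assimilation, Gcn4 amino acid synthesis, ribosomal proteins, ribosome biogenesis, iron, zinc and phosphate regulon, proteasome, respiration, autophagy and vacuole, pheromone response, MAT alpha markers, MAT a markers, sporulation markers and auxotrophic markers. They were written from general knowledge before the data were examined, as were the comparisons, the named-gene rule and the alternatives below unless stated.

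Alternatives changed 1 choice at a time, except that normexp changed the spot signal, the background model and the offset together, and the authors' table changed the scaling and the set of probes. They were normexp with an offset of 50 in place of the processed signal, quantile or median scaling, no brightness filter, a filter on all 15 arrays, the brightest probe per gene and the authors' table. Further alternatives were slide as a fixed or random block, fits within a slide, replicate number as a block, trend and robust settings, array weights, only the 2 groups compared, a threshold of 0.01, a 2-fold threshold and leaving out each array in turn. The mean spot signal planned for normexp is absent from the files, so the median spot signal was used. Chosen after seeing the data were spike-in scaling (to 5 of the 10 E1A spike-in probes, those above background on all arrays), leaving out population outlier spots (572 to 1467 per array), the list and overlap tests without each array or within a slide, the slope over the ER lists, and alternatives of the 2-fold counts.

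The steps were tested on simulated data, in which 50 genes per fold were changed among 6095. At a true 1.2-fold change 76% to 90% were called with the right sign, and at 2-fold 96% to 100%. False calls made up 3.96% to 7.18% of calls, and the changed list was found each time. All genes of that list were raised 2-fold, so finding it was all but certain. The noise was drawn independently per gene and without a slide effect. The simulation thus covers neither correlated list members (estimated correlation 0.57 for ribosomal proteins) nor the layout of the slides.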

Results

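Transcript levels were measured in budding yeast, Saccharomyces cerevisiae of the W303 background, on 15 single-colour (Cy3) Agilent arrays. There were 5 groups of 3 arrays each. They were untreated wild type (WT), WT treated with 2 mM dithiothreitol (DTT) for 1 h, and strains lacking ALG5, LHS1 or SCJ1, called alg5, lhs1 and scj1 here. DTT reduces disulfide bonds and so disturbs protein folding in the endoplasmic reticulum (ER). The triplicates were independent cultures according to the series text, and the number of arrays limits the precision of every value. The study's title places the arrays in work on the unfolded protein response (UPR), the transcriptional programme that follows misfolding in the ER, as a pathway that compensates for many defects.

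Each array held 61657 yeast spots for 6616 yeast probes. The 75th percentile of yeast signal ran from 6487 intensity units on a WT array to 12419 on a DTT array, and between 89.0% and 94.5% of yeast probes lay well above background. No yeast spot was saturated on any array (0 of the 61657 yeast spots). Of 6572 genes, 6095 were bright enough to be tested. The median replicate SD was 0.03 log2 in WT, DTT and lhs1, 0.04 in alg5 and 0.05 in scj1. Arrays lay on 2 slides. The first held WT, DTT and alg5 replicate 1, and the second held the other alg5 arrays, lhs1 and scj1. The alg5 group alone joins the slides, so values with slide as a term are given beside those of the strains.

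The deleted genes were the first check of the labels. ALG5 (YPL227C) encodes the glucosyltransferase that makes dolichol-phosphate-glucose for N-glycans, LHS1 (YKL073W) an Hsp70-like nucleotide exchange factor of the ER chaperone Kar2, and SCJ1 (YMR214W) a DnaJ-type partner of Kar2. ALG5 was at least 151-fold lower in alg5 than in WT (adjusted p = 1.9e-12), LHS1 at least 486-fold lower in lhs1 (adjusted p = 1.6e-13) and SCJ1 at least 320-fold lower in scj1 (adjusted p = 3.3e-10). Each was well above background on 0 of 3 arrays of its own strain and on 3 of 3 WT arrays. LHS1 rose in DTT by 1.89 log2 (SE 0.18, adjusted p = 4.4e-07) and in scj1 by 1.07 (adjusted p = 0.00047), each on 3 of 3 arrays. In alg5 LHS1 was 0.37 log2 higher without passing (adjusted p = 0.10), but passed when only alg5 and WT were fitted (adjusted p = 0.00026). Its alternatives there ran from 7.5e-06 with normexp background correction to 0.27.

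SCJ1 rose in DTT by 1.38 log2 (SE 0.33, adjusted p = 0.0018). In lhs1 it was 0.46 log2 higher without passing (adjusted p = 0.26), but passed when only lhs1 and WT were fitted (adjusted p = 1.7e-05, other alternatives up to 0.55). In alg5 SCJ1 was 0.20 log2 higher without passing (adjusted p = 0.63), with 0.0027 for alg5 and WT alone and up to 0.76 elsewhere. The fit over all arrays takes in the noise of each deleted gene below background in its own strain. ALG5 did not pass in DTT (−0.07 log2, adjusted p = 0.69), in lhs1 (−0.10, adjusted p = 0.63) or in scj1 (0.01, adjusted p = 0.97). It was higher with slide as a block, by 0.60 log2 in lhs1 (adjusted p = 0.027) and by 0.71 in scj1 (adjusted p = 0.016), since that slide term rests on the strain without ALG5. Other alternatives went up to 0.88 and 0.99. With spike-in scaling ALG5 was 0.62 log2 higher in DTT (adjusted p = 0.0021, other alternatives up to 0.78).

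**Figure D1:**
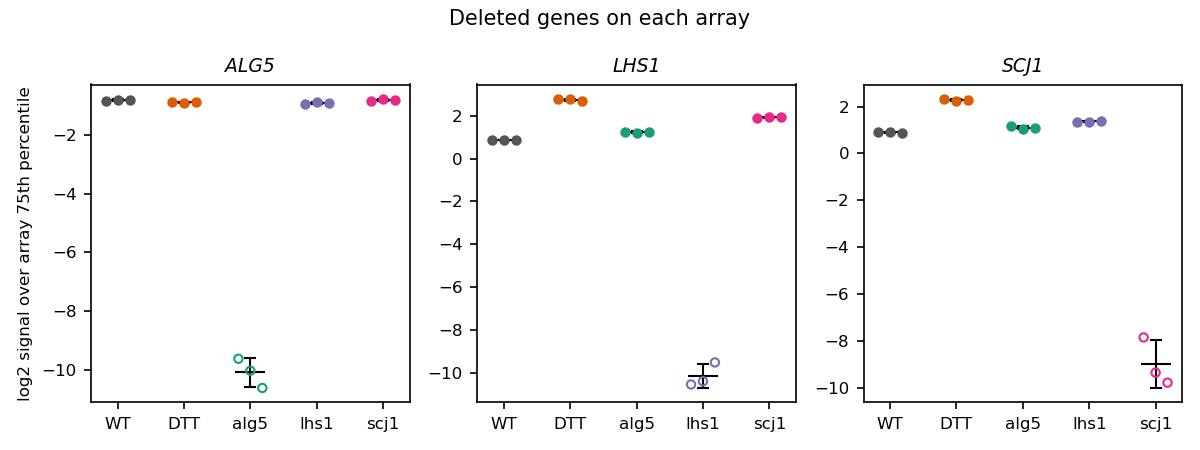
Log2 signal of ALG5, LHS1 and SCJ1 over the 75th percentile of the same array, for 3 arrays in each of WT, DTT, alg5, lhs1 and scj1; points are arrays, bars are means with SD, and open points are arrays where the gene was not well above background. Each gene is open on 0 of 3 WT arrays and on 3 of 3 arrays of its own strain, and LHS1 averages 0.85 in WT, 2.74 in DTT and 1.92 in scj1.

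DTT against WT shows the response to an acute folding defect. Some ER chaperone and oxidase genes rose. The transcripts of the Kar2 exchange factor SIL1 (YOL031C) rose by 2.92 ± 0.03 log2 (SE of the difference, n = 3 arrays in each group, here and throughout), 7.57-fold. The thiol oxidase ERO1 (YML130C) rose by 2.63 ± 0.03 and the disulfide isomerase homologue EUG1 (YDR518W) by 2.63 ± 0.03. KAR2 (YJL034W), the main ER Hsp70, rose by 1.75 ± 0.05 log2, 3.37-fold, and the disulfide isomerase PDI1 (YCL043C) by 1.58 ± 0.04. DER1 (YBR201W), which acts in ER-associated degradation, rose by 2.17 ± 0.03, and HAC1 (YFL031W), which encodes the transcription factor of the UPR, by 1.06 ± 0.08. The largest adjusted p among these was 2.4e-08 for HAC1, and in each case 3 of 3 DTT arrays lay above all 3 WT arrays.

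Of the 6095 genes, 5245 passed the threshold in DTT, with 2704 higher and 2541 lower. At least 2-fold changes passed for 341 higher and 354 lower genes, and at least 4-fold changes for 66 and 31. The 3 arrays of DTT lay all on one side of those of WT for 89.2% of genes, where chance gives 10%. The largest increase was that of ULI1 (YFR026C), a UPR-inducible gene, at 5.42 ± 0.04 log2 (42.8-fold, adjusted p = 6.8e-17). RTA1 (YGR213C), linked to resistance to 7-aminocholesterol, followed at 5.36 ± 0.12. Next came YOL037C (4.82 ± 0.06), YET2 (YMR040W, an ER membrane protein, 4.24 ± 0.04), YLR349W (3.99 ± 0.08, well above background on 2 of 3 WT arrays), MNC1 (YBR056W-A, 3.91 ± 0.06) and YBL065W (3.60 ± 0.05). With normexp the increases of YOL037C and YBL065W were 3.25 and 2.27 log2. YJL152W, below background in WT, was at least 14.9-fold higher.

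The largest decreases in DTT were YER053C-A (−3.95 ± 0.11 log2), the cell wall mannoprotein gene HPF1 (YOL155C, −3.47 ± 0.06), CSS1 (YIL169C, −3.38 ± 0.06) and the hexose transporter gene HXT4 (−3.37 ± 0.04). They were followed by RPL7B (−3.35 ± 0.06), HXT7 (−3.23 ± 0.15), HXT6 (−3.10 ± 0.14) and the proline permease gene PUT4 (−2.98 ± 0.09). HXT6 and HXT7 are near-identical, so their probes may read the same transcripts. Among these 8 genes the largest adjusted p was 2.0e-10, that of HXT6.

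The ER lists rose in DTT. In the ER folding list 17 of 19 genes rose and 1 fell (median 1.38 log2, camera adjusted p = 1.9e-05, but 0.14 with an estimated correlation), led by SIL1, EUG1, ERO1 and MPD1 (2.47). In ER-associated degradation 17 of 19 rose and 1 fell (median 0.58, adjusted p = 5.5e-05), led by DER1, DFM1 (1.56) and HRD1 (1.55). In N-glycosylation 28 of 33 rose and 2 fell (median 0.32, adjusted p = 3.4e-05), with SEC59 at 1.33, PMI40 at 1.30 and ALG6 at 1.25. In ER to Golgi transport 37 of 43 rose and 6 fell (median 0.46, adjusted p = 6.4e-06), with the cargo receptor gene ERV29 at 1.77 and SFB2 at 1.45. These last 3 lists held with an estimated correlation (adjusted p = 0.034, 0.032 and 0.038).

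Further ER lists passed only with the preset correlation. O-mannosylation had 9 of 11 genes higher and 1 lower (median 0.21 log2, adjusted p = 0.013, 0.16 with an estimated correlation), led by the mannosyltransferase genes PMT3 (2.28) and PMT5 (1.62). GPI anchor synthesis had 15 of 21 higher and 1 lower (median 0.24, adjusted p = 0.011, 0.18 with an estimated correlation), led by MCD4 (2.68) and GWT1 (1.22). ER translocation had 15 of 24 higher and 4 lower (median 0.12, adjusted p = 0.039, 0.31 with an estimated correlation), with SEC62 and SEC66 at 1.08. That call was lost within the first slide alone (adjusted p = 0.079). The translocon gene SEC61 rose by 0.60 ± 0.03. The UPR signalling list did not pass (2 of 5 higher and 2 lower, adjusted p = 0.88). Its median and mean were above 0 (0.01 and 0.04 log2) while the test pointed down. In it the HAC1 transcript rose and the phosphatase gene PTC2 fell by 0.82 log2. PTC2 lost its call with spike-in scaling (−0.12, adjusted p = 0.073, from a range of 6.5e-13 to 0.073 over the alternatives).

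In DTT 130 of 131 ribosomal protein genes fell and 1 rose (median −1.08 log2, adjusted p = 3.0e-26, 0.18 with an estimated correlation), 106 of them at least 2-fold, with RPL7B and RPL8A (−2.66) in front. All 49 ribosome biogenesis genes fell (median −0.79, adjusted p = 8.6e-13, 0.18 with an estimated correlation), among them NSR1 (−1.19) and SDA1 (−1.09). In respiration 40 of 42 fell and 0 rose (median −0.76, adjusted p = 3.6e-11, 0.18 with an estimated correlation), with cytochrome c gene CYC1 at −1.73. Amino acid synthesis genes under Gcn4 fell in 32 of 34 cases (median −0.67, adjusted p = 7.5e-09, 0.054 with an estimated correlation), with ARG3 at −2.90 and HIS4 at −1.60. Sulfur assimilation fell in 24 of 26 cases and rose in 0, or 1 when adjusted over the list alone (median −0.76, adjusted p = 2.4e-07, 0.17 with an estimated correlation), with MET5 at −1.60. All 7 genes specific to MAT a cells fell (median −0.96, adjusted p = 0.0013, 0.18 with an estimated correlation), MFA2 by 1.73. With spike-in scaling these falls shrank or were absent, with medians of −0.39 for ribosomal proteins, −0.27 for MAT a genes, −0.10 for ribosome biogenesis, −0.07 for respiration and for sulfur assimilation and 0.02 log2 for the Gcn4 list.

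Proteasome genes rose in 33 of 34 cases in DTT (median 0.44 log2, adjusted p = 3.3e-08, 0.032 with an estimated correlation), with PRE3 at 0.68. In autophagy and vacuole 16 of 17 rose (median 0.57, adjusted p = 0.00014, 0.29 with an estimated correlation), led by the mannosidase gene AMS1 (2.75). General stress genes rose in 16 and fell in 4 of 25 cases (median 0.46, adjusted p = 0.036, 0.64 with an estimated correlation and 0.68 with spike-in scaling), with PHM7 at 1.94 and glycogen phosphorylase gene GPH1 at −1.75. Sporulation markers rose in 10 and fell in 1 of 13 cases (median 0.42, adjusted p = 0.031, 0.18 with an estimated correlation), led by the meiotic chromosome gene HOP1 (3.26). That call was lost with quantile scaling (adjusted p = 0.094) and with spike-in scaling (0.16). Auxotrophic markers fell in 6 and rose in 1 of 7 cases (median −0.51, adjusted p = 0.046, 0.18 with an estimated correlation), with URA3 at −1.22. That call was lost without DTT replicate 3 (adjusted p = 0.051), with slide as a block (0.051), with quantile scaling (0.058) and with spike-in scaling (0.077), which also turned the median to 0.18.

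The other lists did not pass in DTT. In inositol and phospholipid synthesis 5 of 19 rose and 12 fell (median −0.31 log2, adjusted p = 0.067). Inositol-phosphate synthase gene INO1 (YJL153C) rose by 2.69 ± 0.24 while the choline transporter gene HNM1 fell by 1.30. In ergosterol synthesis 8 of 24 rose and 13 fell (adjusted p = 0.32). Cell wall integrity genes split into 11 higher and 12 lower of 24 (adjusted p = 0.89, median −0.07 and mean 0.09). The glucan synthase gene GSC2 (YGR032W) rose by 3.34 ± 0.04 and the wall protein gene CWP1 fell by 2.27. Heat shock genes split into 9 higher and 12 lower of 24 (adjusted p = 0.89, median −0.13 and mean 0.10), and quantile scaling turned the list upwards (median 0.26, adjusted p = 0.034). Redox genes under Yap1 rose in 15 and fell in 9 of 28 cases (adjusted p = 0.16, 0.017 with quantile scaling), with glutathione peroxidase gene GPX2 at 1.74.

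Iron regulon genes rose in 14 and fell in 5 of 23 cases in DTT (adjusted p = 0.058), led by TIS11 (3.47), an RNA decay factor of the iron response. Zinc regulon genes rose in 4 and fell in 5 of 12 (adjusted p = 0.89, median 0.04 and mean −0.02). Phosphate regulon genes rose in 7 and fell in 8 of 18 (adjusted p = 0.72), with the phosphate transporter gene PHO84 (YML123C) at −2.31 and the regulator gene SPL2 (YHR136C) at −2.41. Pheromone response genes rose in 9 and fell in 6 of 17 (adjusted p = 0.66), with PRM4 at 2.67 and FAR1 at −1.81. MAT alpha markers rose in 2 and fell in 1 of 4 cases (adjusted p = 0.78, median 0.17 and mean −0.05), with STE3 at 1.49.

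The scale of the DTT arrays needs a value beside these counts. The 75th percentile of yeast signal, to which all values are relative, was 0.69 log2 higher over the spike-in signal in DTT than in WT. With spike-in scaling 4995 genes were higher and 510 lower. The medians of the inositol (0.38), ergosterol (0.56), cell wall (0.63), heat shock (0.57) and phosphate (0.68) lists were then above 0. The ribosomal protein list stayed below it (−0.39) and the ER folding list stood at 2.07 log2.

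**Figure D2:**
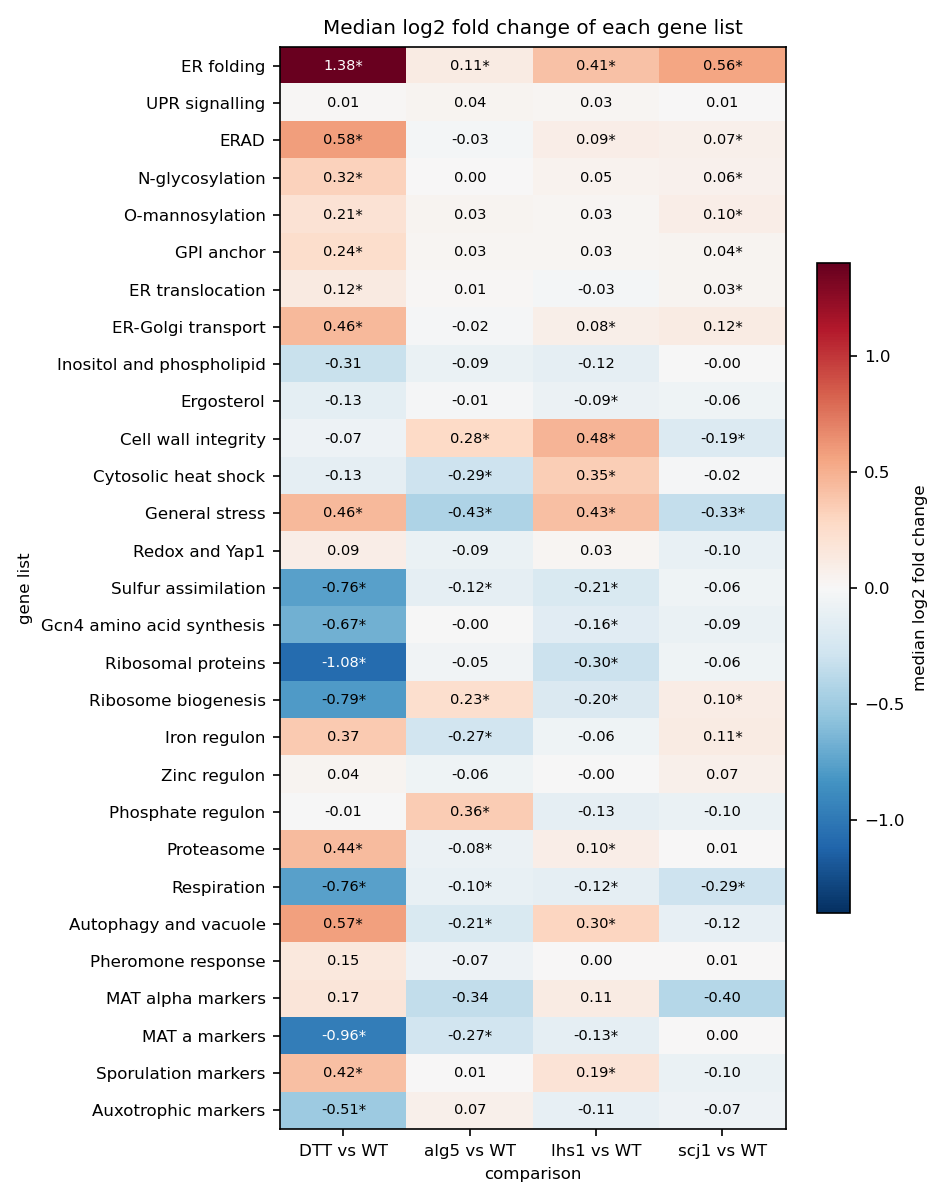
Median log2 fold change against WT (colour) of 29 gene lists in DTT, alg5, lhs1 and scj1, 3 arrays in each group; a star marks a camera adjusted p under 0.05. ER folding reads 1.38, 0.11, 0.41 and 0.56, ribosomal proteins −1.08, −0.05, −0.30 and −0.06; with spike-in scaling the DTT medians of the Gcn4, auxotrophic, inositol, ergosterol, cell wall, heat shock and phosphate lists lie above 0.

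The alg5 strain tests the loss of the glucose donor of N-glycans. ERO1 rose by 0.57 ± 0.03 log2 (adjusted p = 7.9e-08), SIL1 by 0.47 ± 0.03 (adjusted p = 2.9e-07) and KAR2 by 0.26 ± 0.05 (1.2-fold, adjusted p = 0.00042). The 8 largest increases included 4 phosphate genes, with SPL2 at 2.26 ± 0.14 (adjusted p = 1.1e-07), the transporter genes PHO89 at 2.03 ± 0.08 and PHO84 at 2.00 ± 0.18, and the acid phosphatase gene PHO5 (YBR093C) at 1.69 ± 0.08. OSI1 (YKL071W) ranked first at 2.28 ± 0.07, or 1.29 with normexp. RTA1 (1.85 ± 0.12), MNC1 (1.57 ± 0.06) and YLR460C (1.56 ± 0.05) completed the 8 largest. For each of these, 3 of 3 alg5 arrays lay above all WT arrays.

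After ALG5 itself, the largest decreases in alg5 were those of the sphingoid base exporter gene RSB1 (−2.53 ± 0.30, above background on 1 of 3 alg5 arrays), RRT5 (−2.30 ± 0.11) and the zinc transporter gene ZRT1 (−2.24 ± 0.14). YGR035C (−2.21 ± 0.19), SPO19 (−2.10 ± 0.15, above background on 1 of 3 alg5 arrays), MOR1 (YDR366C, −1.98 ± 0.13) and YPR002C-A (−1.93 ± 0.12) followed. With normexp the decreases shrank to −1.04 for RSB1, −1.55 for RRT5, −0.96 for SPO19, −1.23 for MOR1 and −0.96 for YPR002C-A. Passing genes numbered 3348, with 1240 higher and 2108 lower. Quantile scaling gave 1685 and 1695, and spike-in scaling 430 and 2335. At least 2-fold changes passed for 19 higher and 28 lower genes. The fit with slide as a block called 2602 genes, 99.9% of the called genes kept their sign, and 16 and 34 genes changed at least 2-fold. Within the first slide 2761 passed, from 1 alg5 array that is assumed to vary like the WT and DTT arrays.

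In alg5 the ER folding list rose by a small amount, with 9 of 19 genes higher and 3 lower, or 10 and 3 when adjusted over the list alone (median 0.11 log2, 0.09 with slide as a block, adjusted p = 0.00092, 0.28 with an estimated correlation). With spike-in scaling the median of the list was 0.03 log2. JEM1 (0.46) and FPR2 (0.45) followed ERO1 and SIL1. EUG1 rose by 0.25 (adjusted p = 2.7e-05), which did not pass with spike-in scaling (0.17, adjusted p = 0.059, alternatives 5.5e-06 to 0.059). PDI1 was 0.11 higher (adjusted p = 0.044), which was lost on leaving out any 1 array (adjusted p = 0.051 to 0.14) and with slide as a block (0.09, adjusted p = 0.30, alternatives 0.010 to 0.76). HRD1 was 0.11 higher (adjusted p = 0.0063), lost with slide as a block (0.07, adjusted p = 0.16) and with spike-in scaling (0.02, adjusted p = 0.77, the highest of a range from 0.00012). HAC1 did not pass (0.02, adjusted p = 0.87) and was lower within the first slide (−0.16, adjusted p = 0.013, alternatives up to 0.97), where alg5 has 1 array that is assumed to vary like the WT and DTT arrays. INO1 (−0.04, adjusted p = 0.89) and SEC61 (0.02, adjusted p = 0.52) did not pass.

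No other ER list passed in alg5. ER-associated degradation had 3 of 19 genes higher and 6 lower (adjusted p = 0.70), with DER1 at 0.24. N-glycosylation had 6 of 33 higher and 7 lower, 6 when adjusted over the list alone, ALG5 among them (adjusted p = 0.61, median 0.00 and mean −0.28 log2). O-mannosylation had 3 of 11 higher and 1 lower (adjusted p = 0.36), GPI anchor synthesis 7 of 21 and 4 (adjusted p = 0.077, MCD4 at 0.47). ER translocation had 6 of 24 higher and 2 lower, 1 when adjusted over the list alone (adjusted p = 0.11). ER to Golgi transport had 9 of 43 higher and 10 lower, 8 when adjusted over the list alone (adjusted p = 0.36, median and mean below 0 and the test pointing up). UPR signalling had 2 of 5 higher and 0 lower (adjusted p = 0.24).

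Cell wall and phosphate genes rose in alg5. In cell wall integrity 19 of 24 genes rose and 2 fell (median 0.28 log2, 0.28 with slide as a block, adjusted p = 4.2e-10, 0.053 with an estimated correlation), with GSC2 (1.02), the protease gene YPS3 (0.87) and PRM5 (0.82) among them. In the phosphate regulon 14 of 18 rose and 2 fell (median 0.36, 0.34 with slide as a block, adjusted p = 9.8e-09, 0.053 with an estimated correlation). In ribosome biogenesis 46 of 49 rose and 0 fell (median 0.23, 0.25 with slide as a block, adjusted p = 5.8e-18, 0.22 with an estimated correlation), with the helicase genes DBP2 at 0.47 and DBP7 at 0.38. Ribosomal protein genes were 2 higher and 17 lower of 131, and 0 and 0 when adjusted over the list alone (adjusted p = 0.36).

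Stress, iron and proteasome genes fell in alg5. Heat shock genes fell in 20 and rose in 1 of 24 cases, 2 when adjusted over the list alone (median −0.29 log2, −0.31 with slide as a block, adjusted p = 3.2e-06, 0.21 with an estimated correlation), with the small heat shock gene HSP42 at −1.07 and the Hsp90 gene HSP82 at −0.90. General stress genes fell in 21 of 25 cases and rose in 0 (median −0.43, −0.44 with slide as a block, adjusted p = 8.5e-06, 0.42 with an estimated correlation), with hexokinase gene HXK1 at −1.54. Iron regulon genes fell in 18 of 23 cases and rose in 0 (median −0.27, −0.29 with slide as a block, adjusted p = 9.9e-05, 0.22 with an estimated correlation), with the reductase gene FRE1 at −1.43. Proteasome genes fell in 23 of 34 cases (median −0.08 with and without slide as a block, adjusted p = 0.00061, 0.21 with an estimated correlation), RPN4 by 0.27. Respiration genes fell in 24 of 42 cases (median −0.10, −0.11 with slide as a block, adjusted p = 0.0070, 0.61 with an estimated correlation), CIT1 by 0.33. MAT a markers fell in 6 of 7 cases (median −0.27, −0.33 with slide as a block, adjusted p = 0.016, 0.42 with an estimated correlation).

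Other calls in alg5 depended on single arrays. Autophagy genes fell in 12 and rose in 2 of 17 cases (median −0.21, −0.28 with slide as a block, adjusted p = 0.029, 0.61 with an estimated correlation), with APE1 at −0.68. That call was lost without WT replicate 2 (adjusted p = 0.052) and with spike-in scaling (0.095). Sulfur assimilation fell in 17 and rose in 1 of 26 cases (median −0.12, adjusted p = 0.017, 0.55 with an estimated correlation), with MUP3 at −0.41. That call was lost without alg5 replicate 2 (adjusted p = 0.057) and with slide as a block (median −0.10, adjusted p = 0.077). The lists that did not pass were inositol (3 of 19 higher and 9 lower, adjusted p = 0.36), ergosterol (5 of 24 and 7, or 5 and 6 when adjusted over the list alone, adjusted p = 0.63) and zinc (1 of 12 and 5, adjusted p = 0.36, ZPS1 at −0.93). Redox genes were higher in 5 and lower in 14 of 28 cases (adjusted p = 0.72, median −0.09 and mean 0.03), with the oxidoreductase gene OYE3 at 1.38. Gcn4 targets were 9 higher and 5 lower of 34 (adjusted p = 0.23). Pheromone response genes were 2 higher and 8 lower of 17 (adjusted p = 0.32, FUS1 at −1.18), MAT alpha markers 0 and 4 of 4 (adjusted p = 0.13), sporulation markers 6 and 2 of 13 (adjusted p = 0.20) and auxotrophic markers 3 and 3 of 7 (adjusted p = 0.61).

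The lhs1 strain tests the loss of one of the exchange factors of Kar2. ERO1 rose by 1.43 ± 0.03 log2 (2.70-fold, adjusted p = 3.7e-12), SIL1, the other exchange factor of Kar2, by 1.32 ± 0.03, and KAR2 by 1.11 ± 0.05 (2.16-fold, adjusted p = 6.2e-10). The cytosolic Hsp70 gene SSA4 (YER103W) rose by 2.47 ± 0.02 (adjusted p = 1.0e-17) and the small heat shock gene HSP26 by 2.19. INO1 rose by 2.50 ± 0.24 (adjusted p = 2.4e-06). HAC1 was 0.38 ± 0.08 higher (adjusted p = 0.0010), but 0.12 with slide as a block (adjusted p = 0.43, the highest of a range from 2.5e-06), and SEC61 was 0.08 higher (adjusted p = 0.036), lost with slide as a block (0.06, adjusted p = 0.44, the highest of a range from 0.00012). SEC61 also lost its call without WT replicate 2 (0.06, adjusted p = 0.15), WT replicate 3 (0.061) or any 1 lhs1 array (0.056 to 0.12). PDI1 rose by 0.81, EUG1 by 0.76, DER1 by 0.88, JEM1 by 0.69 and HRD1 by 0.57.

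Large increases in lhs1 were those of RTA1 (3.68 ± 0.12, 12.8-fold) and YPT53 (an endosomal Rab gene, 3.02 ± 0.14). ULI1 (3.0 ± 0.04, 8.0-fold, adjusted p = 5.1e-14), YLR349W (2.91 ± 0.08) and CPP3 (2.70 ± 0.14) also rose. Genes below background in WT were YDL114W, at least 6.29-fold higher, and the thiamine synthesis gene THI13, at least 6.10-fold higher. With normexp YPT53 stood at 1.58 and YLR349W at 1.55 log2. Only 4 genes fell at least 2-fold. They were LHS1, PHO84 (−2.68 ± 0.18, adjusted p = 5.8e-08), SPL2 (−2.18 ± 0.14) and MOR1 (−1.07 ± 0.13), and there were 8 such genes without WT replicate 1 and 7 without lhs1 replicate 2. ZRT1 (−0.97 ± 0.14) and YER046W-A (−1.0 ± 0.14, above background on 2 of 3 lhs1 arrays) followed. YGR035C (−0.93 ± 0.19, adjusted p = 0.0012) and FRE1 (−0.90 ± 0.23, adjusted p = 0.0050) lost their calls with slide as a block, at −0.68 (adjusted p = 0.16, from a range starting at 1.4e-05) and −0.89 (adjusted p = 0.14, from 0.00037).

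In lhs1 3584 genes passed, with 1736 higher and 1848 lower, and 114 were at least 2-fold higher. Quantile scaling gave 1418 higher and 2450 lower, and spike-in scaling 1322 and 613. The fit with slide as a block called 2155, with 1093 higher and 1062 lower, 108 at least 2-fold higher and 3 lower. Of the called genes 98.1% kept their sign. No comparison of lhs1 or scj1 with WT exists within a slide.

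The ER folding list rose in lhs1 (13 of 19 higher and 3 lower, median 0.41 log2, 0.37 with slide as a block, adjusted p = 0.00081, 0.22 with an estimated correlation). Its mean was −0.12, since LHS1 itself is a member. In ER-associated degradation 9 of 19 rose and 2 fell (median 0.09, 0.12 with slide as a block, adjusted p = 0.0016, 0.11 with an estimated correlation), DFM1 by 0.55. In ER to Golgi transport 23 of 43 rose and 9 fell (median 0.08, 0.06 with slide as a block, adjusted p = 0.0076, 0.22 with an estimated correlation), with the lectin gene EMP46 and ERV29 at 0.74. N-glycosylation (13 of 33 higher and 6 lower, adjusted p = 0.15, SEC59 at 0.44), O-mannosylation (5 of 11 and 3, adjusted p = 0.42, PMT3 at 0.66) and GPI anchor synthesis (8 of 21 and 5, adjusted p = 0.38, MCD4 at 1.13) did not pass. N-glycosylation passed with quantile scaling (median 0.02, adjusted p = 0.024). ER translocation had 9 of 24 higher and 8 lower, 9 when adjusted over the list alone (adjusted p = 0.83, median −0.03 and mean 0.03). UPR signalling had 1 of 5 higher, 2 when adjusted over the list alone, and 2 lower (adjusted p = 0.96).

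Stress and cell wall genes rose in lhs1. Heat shock genes rose in 22 of 24 cases and fell in 0 (median 0.35 log2, 0.31 with slide as a block, adjusted p = 8.6e-11, 0.084 with an estimated correlation), with the aggregation factor gene BTN2 at 1.61 and HSP42 at 1.58. Cell wall integrity genes rose in 19 and fell in 2 of 24 cases (median 0.48, 0.51 with slide as a block, adjusted p = 7.9e-09, 0.084 with an estimated correlation), with GSC2 at 2.22, YPS3 at 1.90 and PIR3 at 1.47. General stress genes rose in 17 of 25 cases, 19 when adjusted over the list alone, and fell in 1 (median 0.43, 0.39 with slide as a block, adjusted p = 7.0e-06, 0.29 with an estimated correlation), with DDR2 at 1.98 and HSP12 at 1.60. Autophagy genes rose in 16 of 17 cases (median 0.30, 0.27 with slide as a block, adjusted p = 1.8e-06, 0.22 with an estimated correlation), with AMS1 at 2.15. Proteasome genes rose in 26 of 34 cases (median 0.10, 0.08 with slide as a block, adjusted p = 8.8e-05, 0.11 with an estimated correlation), with the regulator gene RPN4 at 0.26. Sporulation markers rose in 8 and fell in 0 of 13 cases, 1 when adjusted over the list alone (median 0.19, 0.22 with slide as a block, adjusted p = 0.0057, 0.13 with an estimated correlation and 0.12 with quantile scaling), with HOP1 at 2.30.

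Ribosomal protein genes fell in 129 of 131 cases in lhs1 and rose in 1 (median −0.30 log2, −0.29 with slide as a block, adjusted p = 3.5e-26, 0.22 with an estimated correlation). Ribosome biogenesis genes fell in 46 of 49 cases, 48 when adjusted over the list alone (median −0.20, −0.18 with slide as a block, adjusted p = 7.2e-10, 0.28 with an estimated correlation), CBF5 by 0.32. Gcn4 targets fell in 25 and rose in 1 of 34 cases, 27 and 1 when adjusted over the list alone (median −0.16 with and without slide as a block, adjusted p = 1.8e-06, 0.13 with an estimated correlation), LYS20 by 0.45. Sulfur assimilation fell in 21 of 26 cases (median −0.21, −0.19 with slide as a block, adjusted p = 3.2e-06, 0.22 with an estimated correlation), MET5 by 0.36. Respiration genes fell in 28 and rose in 1 of 42 cases, 29 and 1 when adjusted over the list alone (median −0.12, −0.16 with slide as a block, adjusted p = 2.2e-05, 0.36 with an estimated correlation and 0.069 with quantile scaling). Ergosterol genes fell in 12 and rose in 1 of 24 cases (median −0.09, adjusted p = 0.0091, 0.27 with an estimated correlation), with ERG25 at −0.25. That call was lost with slide as a block (−0.10, adjusted p = 0.059) and with quantile scaling (0.87). MAT a markers fell in 6 of 7 cases, 7 when adjusted over the list alone (median −0.13, −0.25 with slide as a block, adjusted p = 0.015, 0.30 with an estimated correlation).

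The remaining lists did not pass in lhs1. Inositol genes were higher in 3 and lower in 10 of 19 cases (adjusted p = 0.10, median −0.12 and mean 0.01). Redox genes were 11 higher and 6 lower of 28 (adjusted p = 0.13, 0.0020 with quantile scaling, OYE3 at 1.02). Iron genes were 6 and 10 of 23 (adjusted p = 0.40), with TIS11 at 0.74 and FRE1 at −0.90, and zinc genes 2 and 5 of 12 (adjusted p = 0.41). Phosphate genes were 5 and 11 of 18 (median −0.13, adjusted p = 0.13, 0.042 with spike-in scaling), with PHO84 and SPL2 down. Pheromone genes were 5 and 5 of 17 (adjusted p = 0.96, median 0.00 and mean 0.07 with the test pointing down), MAT alpha markers 2 and 1 of 4 (adjusted p = 0.23, STE3 at 1.79) and auxotrophic markers 1 and 5 of 7 (adjusted p = 0.15).

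The scj1 strain tests the loss of an ER co-chaperone. ERO1 rose by 1.41 ± 0.03 log2 (2.66-fold, adjusted p = 1.4e-11), SIL1 by 1.4 ± 0.03, the GPI anchor enzyme gene MCD4 (YKL165C) by 1.29 ± 0.03, the disulfide isomerase homologue gene MPD1 by 1.28 ± 0.03, JEM1, another DnaJ-type partner of Kar2, by 1.09 ± 0.06 and KAR2 by 1.09 ± 0.05 (2.13-fold, adjusted p = 2.5e-09). The largest increases were YLR349W (1.72 ± 0.08, 0.77 with normexp), YGR039W (1.67 ± 0.04), YGR122C-A (1.67 ± 0.11), HOP1 (1.41 ± 0.04), ERO1, YOR192C-C (1.41 ± 0.07), SIL1 and the autophagy gene ATG17 (1.34 ± 0.03). HAC1 did not pass (0.00, adjusted p = 0.97). SEC61 rose by 0.34 ± 0.03 (adjusted p = 2.9e-06). INO1 was 1.18 ± 0.24 higher (adjusted p = 0.0017), between 0.80 and 1.41 on leaving out 1 array, and lost its call with slide as a block (1.18, adjusted p = 0.077, the highest of a range from 0.00036).

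Passing genes in scj1 numbered 2888, with 962 higher and 1926 lower. Quantile scaling gave 1474 and 1415, and spike-in scaling 1837 and 400. At least 2-fold changes passed for 17 higher and 87 lower genes, but 28 of those 87 lay well above background on all 15 arrays. With normexp 18 genes fell at least 2-fold. A slide block left 1689 genes, with 504 higher and 1185 lower, 13 at least 2-fold higher and 52 lower, and 98.9% of the called genes kept their sign.

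After SCJ1, the largest decreases in scj1 lay near background. YOR314W-A was at least 6.85-fold lower (adjusted p = 0.0028), YBL108W at least 5.84-fold (adjusted p = 0.017), RRT7 at least 5.17-fold (adjusted p = 0.0032), YAL067W-A at least 1.90-fold (adjusted p = 0.0011) and YFL012W-A at least 1.56-fold (adjusted p = 0.0087). The monopolin gene MAM1 fell by 3.35 ± 0.62 log2 (adjusted p = 0.00083) and YLR412C-A by 3.33 ± 0.69 (above background on 1 of 3 scj1 arrays). Replicates of alg5, and for some genes those of lhs1, differed widely here too, with SDs in alg5 and lhs1 of 3.15 and 2.95 for YBL108W, 2.57 and 1.48 for RRT7 and 1.79 and 0.42 for MAM1. All 7 lost their calls with slide as a block, with adjusted p from 0.090 for YAL067W-A to 0.54 for YBL108W, where the other alternatives went down to 4.2e-06. With normexp YFL012W-A stood at −0.88, YAL067W-A at −0.75 and MAM1 at −2.32. The phosphate genes PHO84 (−2.0 ± 0.18) and SPL2 (−1.79 ± 0.14) fell on all 3 arrays.

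All 7 ER lists passed upwards in scj1, and UPR signalling, counted apart, did not pass. ER folding had 13 of 19 genes higher and 1 lower, 2 when adjusted over the list alone (median 0.56 log2, 0.52 with slide as a block, adjusted p = 1.3e-09), with a mean of 0.05 that includes SCJ1. ER-associated degradation had 10 of 19 higher and 1 lower (median 0.07, 0.08 with slide as a block, adjusted p = 2.3e-05), with DER1 at 0.74 and DFM1 at 0.67. N-glycosylation had 16 of 33 higher, 18 when adjusted over the list alone, and 3 lower (median 0.06, 0.13 with slide as a block, adjusted p = 1.4e-07), with SEC59 at 0.58 and the dolichol-phosphate-mannose synthase gene DPM1 at 0.45. O-mannosylation had 7 of 11 higher and 1 lower (median 0.10, 0.16 with slide as a block, adjusted p = 3.3e-05), with PMT3 at 0.72, PMT2 at 0.60 and PMT1 at 0.58. ER to Golgi transport had 27 of 43 higher, 29 when adjusted over the list alone, and 5 lower (median 0.12, 0.10 with slide as a block, adjusted p = 1.3e-09), with ERV29 at 0.60. These 5 lists held with an estimated correlation (adjusted p from 0.011 to 0.027). GPI anchor synthesis had 9 of 21 higher and 1 lower (median 0.04, 0.03 with slide as a block, adjusted p = 0.00021, 0.088 with an estimated correlation), with GWT1 at 0.61. ER translocation had 10 of 24 higher and 1 lower (median 0.03, 0.04 with slide as a block, adjusted p = 8.1e-05, 0.11 with an estimated correlation), with SEC62 at 0.58. In UPR signalling 0 of 5 genes were higher and 0 lower (adjusted p = 0.39).

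Respiration genes fell in 42 of 42 cases in scj1 (median −0.29 log2, −0.32 with slide as a block, adjusted p = 1.8e-14, 0.17 with an estimated correlation), with the subunit gene QCR7 of complex III at −0.60 and SDH2 at −0.43. General stress genes fell in 20 of 25 cases and rose in 0 (median −0.33, −0.42 with slide as a block, adjusted p = 0.00073, 0.45 with an estimated correlation), with the glycogen branching enzyme gene GLC3 at −1.02. Cell wall integrity genes fell in 17 and rose in 2 of 24 cases, 3 when adjusted over the list alone (median −0.19, −0.18 with slide as a block, adjusted p = 0.0012, 0.18 with an estimated correlation), with PIR3 at −1.22. With spike-in scaling the medians of these 3 lists shrank to −0.15 for respiration, −0.20 for general stress and −0.05 for the cell wall. Ribosome biogenesis genes rose in 21 and fell in 2 of 49 cases (median 0.10, 0.09 with slide as a block, adjusted p = 9.9e-06, 0.45 with an estimated correlation). Iron regulon genes rose in 13 and fell in 3 of 23 cases (median 0.11, 0.08 with slide as a block, adjusted p = 7.4e-05, 0.17 with an estimated correlation), with the siderophore transporter gene SIT1 at 0.84 and the wall mannoprotein gene FIT2 at −0.73.

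The other lists did not pass in scj1 in the fit with every array. Heat shock genes were higher in 4 and lower in 4 of 24 cases, 4 and 3 when adjusted over the list alone (adjusted p = 0.53, median −0.02 with the test pointing up), with HSP26 at −0.78. Ribosomal protein genes were 0 higher and 9 lower of 131, and 0 and 0 when adjusted over the list alone (median −0.06, adjusted p = 0.10, but 0.0081 without scj1 replicate 1, 0.010 without WT replicate 2 and 0.034 without WT replicate 3). Their median was 0.08 with spike-in scaling. Gcn4 targets were 1 and 16 of 34 (median −0.09, adjusted p = 0.059), and passed without WT replicate 2 (0.045), WT replicate 3 (0.040), scj1 replicate 1 (0.023) or scj1 replicate 3 (0.023), and with quantile scaling (0.0059). In that list SNO1 fell by 1.25 (above background on 1 of 3 scj1 arrays, −0.48 with normexp). Redox genes were 4 and 15 of 28 (adjusted p = 0.070), and passed without WT replicate 3 (0.046) or scj1 replicate 1 (0.035). Inositol genes were 6 and 0 of 19, 5 and 0 when adjusted over the list alone (median −0.00 and mean 0.10, adjusted p = 0.070), and passed without WT replicate 2 (0.036), scj1 replicate 1 (0.010) or scj1 replicate 3 (0.016).

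Phosphate genes were 2 higher and 8 lower of 18 in scj1 (median −0.10, adjusted p = 0.084), and passed without WT replicate 3 (0.029). With spike-in scaling the median turned to 0.04 while the test pointed down (adjusted p = 0.0019). Autophagy genes were 1 and 8 of 17 (adjusted p = 0.15, 0.026 without scj1 replicate 2). Proteasome genes were 4 and 2 of 34, 3 and 2 when adjusted over the list alone (adjusted p = 0.13, 0.042 with spike-in scaling), MAT alpha markers 0 and 3 of 4 (adjusted p = 0.084, 0.0026 with spike-in scaling) and sporulation markers 2 and 5 of 13, 3 and 5 when adjusted over the list alone (adjusted p = 0.37, 0.020 with spike-in scaling). Ergosterol genes were 5 and 13 of 24 (adjusted p = 0.55), sulfur genes 2 and 9 of 26 (adjusted p = 0.55), zinc genes 3 and 3 of 12 (adjusted p = 0.24), pheromone genes 6 and 3 of 17 (adjusted p = 0.17), MAT a markers 2 and 2 of 7 (adjusted p = 0.56) and auxotrophic markers 1 and 3 of 7 (adjusted p = 0.53).

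**Figure D3:**
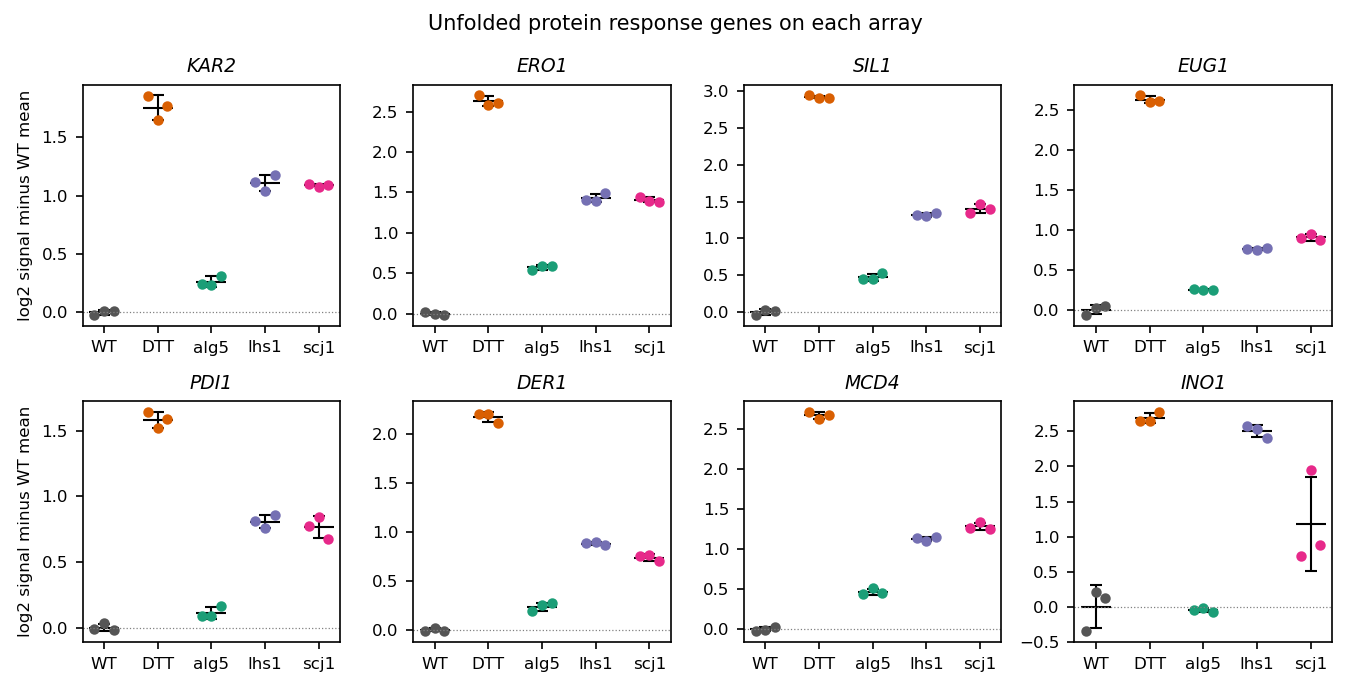
Log2 signal relative to the WT mean for KAR2, ERO1, SIL1, EUG1, PDI1, DER1, MCD4 and INO1 on 3 arrays in each of WT, DTT, alg5, lhs1 and scj1; points are arrays and bars are means with SD. ERO1 averages 2.63 in DTT, 0.57 in alg5, 1.43 in lhs1 and 1.41 in scj1, and INO1 2.69, −0.04, 2.50 and 1.18.

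**Figure D4:**
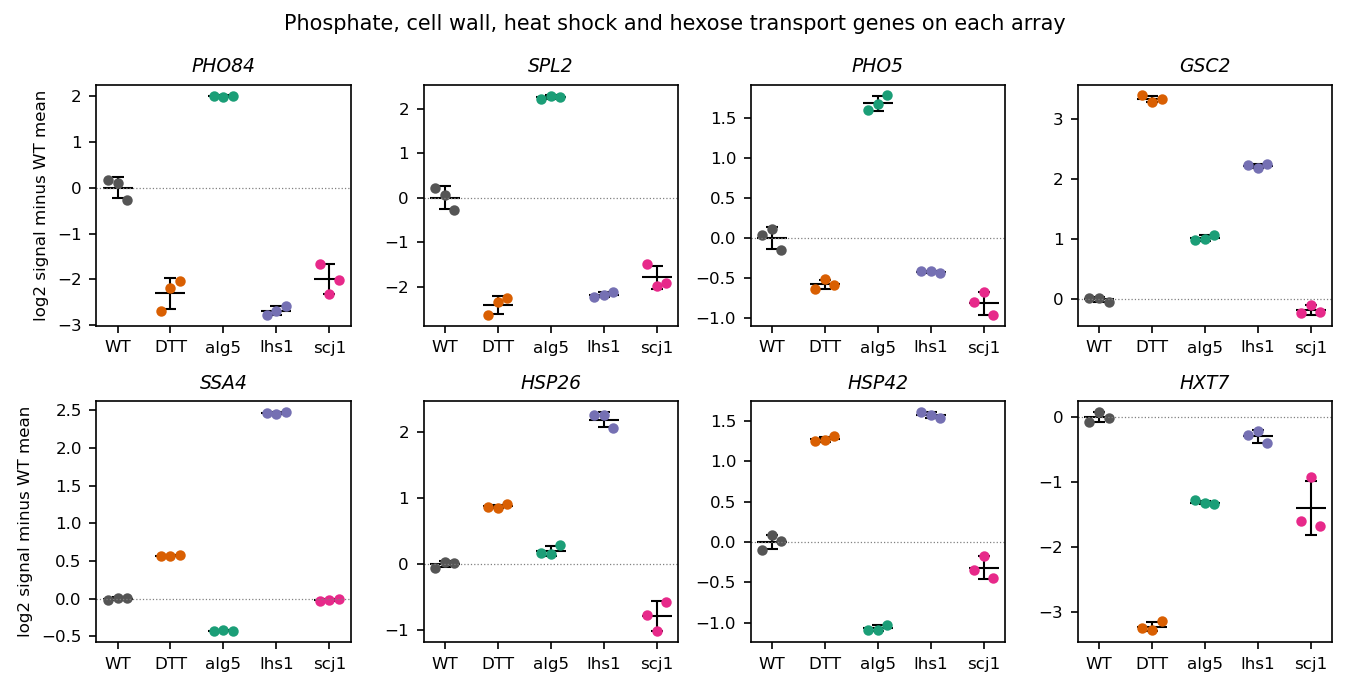
Log2 signal relative to the WT mean for PHO84, SPL2, PHO5, GSC2, SSA4, HSP26, HSP42 and HXT7 on 3 arrays in each of WT, DTT, alg5, lhs1 and scj1; points are arrays and bars are means with SD. PHO84 averages 2.00 in alg5 and −2.68 in lhs1, and SSA4 2.47 in lhs1.

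The knockouts were compared with each other to see where the strains differ. KAR2 was lower in alg5 than in lhs1 by 0.84 ± 0.05 log2 (adjusted p = 8.1e-09) and than in scj1 by 0.82 ± 0.05 (adjusted p = 2.3e-08). Between lhs1 and scj1 it differed by 0.02 (adjusted p = 0.72) and ERO1 by 0.02 (adjusted p = 0.58). With quantile scaling both passed as higher in lhs1, KAR2 by 0.22 (adjusted p = 1.0e-05, other alternatives up to 0.83) and ERO1 by 0.08 (adjusted p = 0.012, others up to 0.87).

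Between alg5 and lhs1 4039 genes passed, with 1599 higher and 2440 lower in alg5, 11 and 151 of them at least 2-fold. Median scaling gave 2506 and 1658. PHO84 was 4.68 ± 0.18 log2 (25.7-fold) and SPL2 4.44 ± 0.14 higher in alg5, with PHO5 at 2.11 ± 0.08 and YLR460C at 2.01 ± 0.05. YDL114W was at least 6.35-fold lower in alg5, ULI1 lower by 3.04 ± 0.04, YPT53 by 3.0 ± 0.14 and SSA4 by 2.89 ± 0.02 (adjusted p = 1.4e-18). All 24 heat shock genes were lower (median −0.68, adjusted p = 2.3e-11, 0.075 with an estimated correlation), as were 24 of 25 general stress genes (median −1.09, adjusted p = 4.2e-08, 0.23 with an estimated correlation). Ribosomal protein genes were higher in 126 of 131 cases (median 0.25, adjusted p = 5.0e-24, 0.23 with an estimated correlation) and ribosome biogenesis genes in 49 of 49 (median 0.43, adjusted p = 1.1e-21, 0.14 with an estimated correlation). ER folding genes were lower in 12 and higher in 2 of 19 cases (median −0.21, mean 0.31 with LHS1, adjusted p = 0.045, 0.41 with an estimated correlation). Blocking by slide left 3906 genes, and within the second slide 3677.

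Between alg5 and scj1 3193 genes passed, with 1587 higher and 1606 lower in alg5, 67 and 20 of them at least 2-fold. With spike-in scaling 303 were higher and 4238 lower. Of the 67, 30 lay above background on every array, and without alg5 replicate 3 there were 44. Apart from the deleted genes SCJ1 and ALG5, SPL2 (4.05 ± 0.14), PHO84 (4.0 ± 0.18), PHO89 (3.08 ± 0.08) and PHO5 (2.50 ± 0.08) were highest in alg5, and ZRT1 (−2.38 ± 0.14), RRT5 (−1.95 ± 0.11) and SPO19 (−1.74 ± 0.15) lowest. Cell wall genes were higher in 22 of 24 cases (median 0.38, adjusted p = 1.2e-13) and phosphate genes in 15 of 18 (median 0.46, adjusted p = 3.2e-09). ER-associated degradation (15 of 19 lower, median −0.15, adjusted p = 1.7e-06), N-glycosylation (24 of 33, −0.13, mean −0.42 with ALG5, 9.6e-07), ER to Golgi transport (26 of 43, −0.12, 2.1e-06), heat shock (23 of 24, −0.29, 1.2e-09) and iron genes (19 of 23, −0.44, 1.5e-08) were lower. These 7 lists held with an estimated correlation (adjusted p from 0.012 to 0.036). ER folding genes were lower in 13 of 19 cases (median −0.37, mean 0.14 with SCJ1, adjusted p = 6.6e-06, 0.073 with an estimated correlation). Blocking by slide left 3076 genes, and within the second slide 2601.

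Between lhs1 and scj1 3869 genes passed, with 2263 higher and 1606 lower in lhs1, 209 and 3 of them at least 2-fold. Quantile scaling gave 1559 and 2662. The 3 lower genes were LHS1, SIT1 (−1.22 ± 0.09) and ZRT1 (−1.11 ± 0.14), and without scj1 replicate 2 there were 6. YPT53 was at least 6.91-fold and YDL114W at least 4.09-fold higher in lhs1, where each was measured, and CPP3 was 3.58 ± 0.14 log2 higher. General stress genes were higher in 25 of 25 cases (median 0.74, adjusted p = 1.7e-08, 0.16 with an estimated correlation), cell wall genes in 21 of 24 (0.66, 5.5e-10, 0.080 with an estimated correlation), heat shock genes in 19 of 24 (0.35, 2.8e-07, 0.14 with an estimated correlation) and autophagy genes in 17 of 17 (0.49, 1.3e-06, 0.16 with an estimated correlation). Ribosomal protein genes were lower in 126 of 131 cases (−0.24, 9.8e-25, 0.16 with an estimated correlation). ER folding genes were lower in 11 and higher in 3 of 19 cases (−0.11, 0.0095, 0.22 with an estimated correlation), with the deleted LHS1 among the lower and the deleted SCJ1 among the higher. N-glycosylation genes were lower in 20 and higher in 4 of 33 (−0.11, 0.00095, 0.11 with an estimated correlation). Blocking by slide left 3947 genes, and within the second slide 3675.

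Each knockout was also set against DTT, to compare a lasting with an acute defect. The ER folding genes were lower than in DTT in 16 of 19 cases in alg5 (median −1.23 log2, adjusted p = 0.00018, 0.18 with an estimated correlation), in 16 in lhs1 (−0.92, 4.6e-06, 0.093 with an estimated correlation) and in 17 in scj1 (−0.78, 0.00034, 0.15 with an estimated correlation). The lists of ER-associated degradation, N-glycosylation and ER to Golgi transport were lower too, with medians of −0.74, −0.38 and −0.48 in alg5 (adjusted p of 9.1e-05 or less, 0.031 to 0.048 with an estimated correlation) and −0.45, −0.32 and −0.41 in lhs1 (1.9e-05 or less, 0.023 with it). In scj1 they were −0.53, −0.26 and −0.37 (0.0014 or less, 0.089 to 0.10 with it). The N-glycosylation list includes the deleted ALG5 in alg5, where the mean of the list was −0.72. The ER folding list includes LHS1 and SCJ1, each deleted in its own strain. KAR2 was lower by 1.49 ± 0.05 in alg5, 0.65 ± 0.05 in lhs1 and 0.67 ± 0.05 in scj1. Ribosomal protein genes were higher than in DTT in 130 of 131 cases in each strain (medians 1.04 in alg5, 0.79 in lhs1 and 1.03 in scj1, adjusted p of 4.1e-26 or less, 0.15 to 0.20 with an estimated correlation). With spike-in scaling the median of all genes moved down by 0.78, 0.66 and 0.56 log2 in these comparisons.

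In alg5 against DTT 5258 genes passed (2358 higher and 2900 lower, or 467 and 5191 with spike-in scaling), with SPL2 at 4.66 and PHO84 at 4.31, and with ULI1 at −5.46 and TIS11 at −4.33 log2. YJL152W was at least 14.6-fold lower. In lhs1 against DTT 5014 passed (2443 and 2571, or 378 and 5143 with spike-in scaling), with YER053C-A at 3.48 and PIR3 at 3.35, and with TIS11 at −2.73 and ULI1 at −2.42. Heat shock genes were higher in lhs1 than in DTT in 21 of 24 cases (median 0.54, adjusted p = 3.1e-05, 0.16 with an estimated correlation). In scj1 against DTT 5261 passed (2288 and 2973, or 603 and 4911 with spike-in scaling), with YER053C-A at 3.46 and the ammonium permease gene MEP2 at 2.88, and with ULI1 at −4.98 and RTA1 at −4.82. With slide as a block 4993, 4254 and 4681 genes passed, and 5116 passed for alg5 within the first slide, again from 1 alg5 array under that assumption.

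Calls against WT were compared. Counts against DTT are read beside its 2704 higher and 2541 lower of 6095 genes. Of the 114 genes at least 2-fold higher in lhs1, 102 were higher in DTT, 77 of them at least 2-fold, where 6.38 such genes were expected by chance. Of the 17 in scj1, 16 were higher in DTT, and of the 19 in alg5, 12 were higher and 6 lower. Of the 87 genes at least 2-fold lower in scj1, 28 were lower in DTT, 12 higher and 47 not called. Of the 87, 20 fell at least 2-fold in DTT, where 5.05 were expected. Of the 28 genes at least 2-fold lower in alg5, 17 were lower in DTT and 5 higher, and of the 4 in lhs1 3 were lower and 1 higher. DTT and lhs1 shared 1502 higher and 1543 lower genes (770 expected each), with 269 opposite. DTT and scj1 shared 673 and 949 (427 and 803 expected), with 899 opposite. DTT and alg5 shared 534 and 877, no more than expected (550 and 879), with 1548 opposite. Among knockouts, alg5 and scj1 shared 460 higher and 1099 lower genes (196 and 666 expected), with 304 opposite. For alg5 and lhs1 there were 490 and 750 (353 and 639 expected), with 913 opposite, and for lhs1 and scj1 507 and 654 (274 and 584 expected), with 689 opposite.

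All overlaps share 3 WT arrays, which cannot be split into separate controls. Part of any excess may come from them or, between knockouts, the slide. Across the 6095 genes, which are not independent replicates, r between fold changes was 0.62 for DTT and lhs1, 0.26 for DTT and scj1, 0.12 for DTT and alg5, 0.34 for alg5 and scj1, 0.16 for alg5 and lhs1 and 0.14 for lhs1 and scj1. In 100 simulations of shared controls alone, without slide effects, r was 0.48 to 0.50 and the covariance near 0.0031. The measured covariance exceeded the simulated one by 0.149 for DTT and lhs1, 0.0543 for DTT and scj1, 0.0193 for DTT and alg5, 0.0269 for alg5 and scj1, 0.0121 for alg5 and lhs1 and 0.0134 for lhs1 and scj1.

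The members of the ER lists were followed from DTT to the knockouts, leaving out the deleted genes. Across 167 such genes the fold change in lhs1 rose with that in DTT with a slope of 0.39 (0.39 with slide as a block, r 0.91, Spearman's coefficient 0.90) and in scj1 with a slope of 0.40 (0.40 with slide as a block, r 0.88, Spearman 0.80). In alg5 the slope was 0.12 (0.12 with slide as a block, r 0.59, Spearman 0.40). Of these genes 80 were higher and 35 lower in lhs1, 91 and 12 in scj1, and 43 and 32 in alg5. The covariance was 0.168 in lhs1, 0.171 in scj1 and 0.0526 in alg5, against 0.00053 from the shared controls. Across the 5342 genes in none of the 29 lists the slope was 0.33 in lhs1 (Spearman 0.74), 0.12 in scj1 (Spearman 0.23) and 0.06 in alg5 (Spearman 0.03). Genes are not independent replicates, so no p is attached to these slopes.

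**Figure D5:**
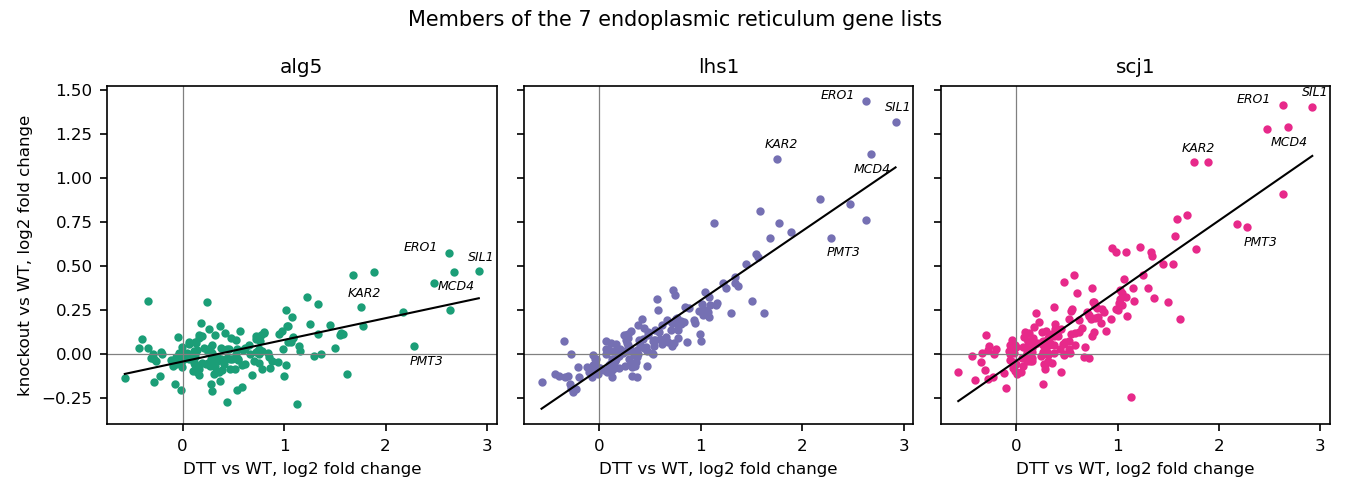
Log2 fold change against WT in alg5, lhs1 and scj1 (vertical axis, one panel each) against that in DTT (horizontal axis) for 167 genes of the ER lists without the deleted genes; points are genes and lines are least-squares fits. The slopes are 0.12 in alg5, 0.39 in lhs1 and 0.40 in scj1, with ERO1, SIL1, MCD4, KAR2 and PMT3 named.

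The label gives the strains as mat alpha, and the mating type genes were read on all arrays. The MAT a genes MFA1, MFA2, STE2, STE6, BAR1, AGA2 and ASG7 were well above background on 15 of 15 arrays, with a median of 8.14 log2 over the array's background floor for the pheromone gene MFA2. The alpha pheromone genes MF(ALPHA)1 and MF(ALPHA)2 were well above background on 6 and 4 of 15 arrays, near the floor (−0.23 and −0.29). The alpha-specific genes SAG1 and AFB1 were well above background on 15 of 15 arrays (medians of 4.71 and 4.94 log2 over the floor) and STE3 on 14 (1.77).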

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

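Only the test for less spike-in RNA was chosen after its result was seen; the test of the summed signal was set before. On the DTT arrays the 75th percentile of yeast signal stood 0.69 log2 higher over the spike-in probes than in WT, a signal outside the main measurement. The smallest DTT value lay 0.54 log2 above the largest WT value, where WT arrays differed by up to 0.19. The differences from WT were −0.085 in alg5, 0.037 in lhs1 and 0.136 in scj1.

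Fewer very abundant transcripts could leave more of the labelled RNA to other genes, and the 100 brightest probes held 33.3% of summed signal in WT and 26.9% in DTT. The summed yeast signal over spike-in rose by 0.365 log2, a share of 0.527 of the shift. The bound set for this explanation was 0.346, and the margin lies inside the SD between DTT arrays (0.0506), so it stays open. Less spike-in RNA in the DTT samples cannot be judged from the spike-in signal. That signal was lower by 0.109 log2 (−0.1094), short of the bound of 0.346 by barely more than its SD between DTT arrays (0.234). The 75th percentile of yeast signal rose by 0.583. Both signals move with the brightness of an array. DTT replicate 2 read 12.054 log2 for the spike-in and 12419 for the 75th percentile. Replicates 1 and 3 read 11.651 and 11.645 with 9794 and 9998. A brighter array could hide a lack of spike-in RNA, so this explanation stays open. A larger amount of labelled yeast RNA in DTT samples, and a change in RNA per cell after DTT, stay open too, and the sources do not say whether spike-in was added per cell or per amount of RNA.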

How the results depend on the processing

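Spike-in scaling, population outliers left out, within-slide and leave-one-out list tests, and alternatives of the 2-fold counts were chosen after the data were seen. Of 319 named gene results under 7449 settings, 7288 kept direction and side of the threshold, 142 lost the call (100 of them from the 2-fold threshold), 16 gained it and 3 turned. Of 116 list results under 1334 settings, 1203 held, 68 were lost, 58 gained and 5 turned. Where no reason is given below, the cause was not tested.

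By its construction the 2-fold threshold reduced calls to 695 in DTT, 47 in alg5, 118 in lhs1 and 104 in scj1 against WT, 162 for alg5 against lhs1, 87 for alg5 against scj1, 212 for lhs1 against scj1, and 770, 322 and 645 for alg5, lhs1 and scj1 against DTT. Calls shared in one direction then fell to 20 for DTT and alg5 (from 1411), 80 for DTT and lhs1 (3045), 33 for DTT and scj1 (1622), 9 for alg5 and lhs1 (1240), 8 for alg5 and scj1 (1559) and 13 for lhs1 and scj1 (1161).

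Slide as a block left 2155 calls in lhs1 and 1689 in scj1, with 52 genes at least 2-fold lower in scj1. Shared calls were 1891 for DTT and lhs1, 1005 for DTT and scj1, 679 for alg5 and lhs1, 852 for alg5 and scj1 and 639 for lhs1 and scj1. The median SE rose from 0.0347 to 0.0599 in lhs1 and scj1 and to 0.0470 in alg5, since the slide term rests on the alg5 arrays. Over probes above background the alg5 pairs across slides differed with SDs of 0.142 and 0.109, and the pair on one slide with 0.158. Across genes, which are not independent replicates, the difference between the slides in alg5 correlated with scj1 minus WT (r 0.2975) and lhs1 minus WT (r 0.1907) more than with DTT minus WT on one slide (r 0.0937), so part of the lhs1 and scj1 differences may come from the slide. ALG5 turned to 0.60 in lhs1 with slide as a block (−0.10 otherwise), which follows from its loss in alg5, and HAC1 in alg5 to −0.16 within the first slide, where the 1 alg5 array is assumed to vary like the WT and DTT arrays. A fit within a slide could not be had for lhs1 or scj1 against WT or DTT. With a replicate block 5226, 3320, 3549 and 2754 genes passed against WT; equal numbers did not pair arrays, since the median r between arrays of equal number was 0.0023 against 0.038 for unequal numbers, and 2 of 15 arrays matched best with their own number.

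Spike-in scaling gave 1935 calls in lhs1. At least 2-fold counts became 1702 higher and 55 lower in DTT, 42 lower for alg5 against scj1 and 5 lower for lhs1 against scj1. Against DTT they became 40 higher and 2328 lower for alg5, 50 and 1110 for lhs1 and 44 and 1377 for scj1. The counts with DTT follow from the 0.69 log2 shift of its arrays. ALG5 turned to 0.62 in DTT.

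With normexp, which shrinks low signals by its construction, at least 2-fold counts were 17 lower in alg5, 69 higher in lhs1, 18 lower in scj1, 88 lower for alg5 against lhs1, 30 higher and 13 lower for alg5 against scj1, 98 higher for lhs1 against scj1 and 253 lower for scj1 against DTT. With genes above background on all 15 arrays there were 28 lower in scj1, 30 higher for alg5 against scj1 and 127 higher for lhs1 against scj1. The authors' table, with fewer probes, gave 42 lower in scj1 and 41 higher for alg5 against scj1. Quantile scaling gave 50 lower in scj1, and 134 higher and 9 lower for lhs1 against scj1. Array weights gave 5 lower for lhs1 against scj1. Leave-one-out counts ran from 3 to 8 genes at least 2-fold lower in lhs1, 44 to 87 higher for alg5 against scj1 and 3 to 6 lower for lhs1 against scj1.

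Of the 29 lists, 18 passed in DTT, 12 in alg5, 16 in lhs1 and 12 in scj1. With an estimated correlation 4 passed in DTT, 0 in alg5, 0 in lhs1 and 5 in scj1. With fry, which does not compare with other genes, 29, 22, 26 and 19 passed. Fry turned the cell wall (median −0.0665) and heat shock (median −0.13) lists upwards in DTT and the redox list (−0.0943) upwards in alg5. It turned N-glycosylation in alg5 downwards (median 0.0018, mean −0.28 with the deleted ALG5). Quantile scaling turned heat shock in DTT upwards (median 0.26).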

Other observations

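Both mating type tests, the step that adds only an offset and the medians per array were chosen after their result was seen, while the tests of dim genes in scj1 and of other splits were set before. The genes in this paragraph were chosen after their values were seen. YGR039W was at least 2-fold higher in DTT (2.25 log2), alg5 (1.08), lhs1 (1.31) and scj1 (1.67), and MOR1 at least 2-fold lower in all 4 (−2.18, −1.98, −1.07 and −2.15). A further 13 genes were at least 2-fold higher in 3 of the 4 comparisons. KAR2, ERO1, SIL1, MCD4, INO1, HOP1, ATG17 and YLR349W did so in DTT, lhs1 and scj1, and GSC2, RTA1, MNC1, NDJ1 and OYE3 in DTT, alg5 and lhs1. The hexose transporter genes HXT7 (−3.23, −1.31 and −1.4) and HXT6 were at least 2-fold lower in DTT, alg5 and scj1. Beside the deleted genes, MUD2 (YKL074C), the neighbour of LHS1, was 1.1 ± 0.03 log2 higher in lhs1 (adjusted p = 1.9e-11) and 1.19 higher in DTT, and CET1, next to ALG5, was 0.40 lower in alg5 (adjusted p = 2.3e-07).

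Of the 87 genes at least 2-fold lower in scj1, 59 were not well above background on every array, the deleted SCJ1 among them, with a median of −1.66 log2 in scj1. With normexp their median was −0.44 and 6 of them were still at least 2-fold lower, but its offset shrinks low signals. Adding the offset alone to the signals used left 13 at least 2-fold lower, so background subtraction on the scj1 arrays and lower transcript levels cannot be told apart. The second slide as the whole cause is argued against by their median of −0.239 in lhs1, which lies on that slide, but a part from the slide or from single arrays stays open. Slide as a block left 52 in place of the 87 genes, and per array the median was −0.82 for lhs1 replicate 1, −1.4 for alg5 replicate 2 and 0.34 for alg5 replicate 3, all on the second slide. Also argued against as the whole cause is a high floor on any array, by their median of −0.571 in DTT, whose mean floor of −7.41 was near that of scj1 (−7.42). DTT replicates 1 and 3, with floors of −7.095 and −7.124, had medians of −0.621 and −0.617, and replicate 2, with −7.999, had −0.515. The genes were picked for low values in scj1, which by itself sets their scj1 median apart from those in lhs1 and DTT. DTT also changed 5245 of 6095 genes, so a part from the floor stays open.

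The labels name mat alpha strains, yet the 7 MAT a markers were well above background in 105 of 105 measurements, which is consistent with RNA from MAT a cells. The 5 alpha-specific genes were so in 54 of 75 measurements, and they did not go together. MF(ALPHA)1 and MF(ALPHA)2 were well above background on 6 and 4 of 15 arrays and STE3 on 14. SAG1 and AFB1 were so on 15 of 15, at medians of 4.71 and 4.94 log2 over the floor. Levels of different probes are not comparable, so these give no share of alpha cells. RNA from a cells alone and from a mixture of a and alpha cells cannot be told apart, since the alpha-specific genes point both ways. No biological explanation was tested, and a wrong label and a change of mating type in the strain cannot be separated either.

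Other splits of the 6 arrays were fitted for each comparison, and 1 of the 10 splits, the real one, gave as many genes each time. Against WT the real split gave 5245 genes in DTT, 3348 in alg5, 2888 in scj1 and 3584 in lhs1, with highest others of 0, 1, 0 and 0. Between knockouts it gave 4039 for alg5 and lhs1 (highest other 4), 3193 for alg5 and scj1 (1) and 3869 for lhs1 and scj1 (0). Against DTT it gave 5258, 5014 and 5261 (highest other 0 each). With 10 splits a share under 0.1 cannot be reached.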
